A study of Homo sapiens with 14 samples.

How the data were processed

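Tumours were grown from A431 cells kept in medium with 10% serum, which were injected under the skin of mice, per the labels' protocols. The same labels state that 6 doses of each treatment were given from day 7 on, and that mice were killed on day 18, 2 hours after the last dose. Total RNA was isolated with TRIzol, and 500 ng per sample was turned into Cy3-labelled cRNA with oligo-dT priming, at 40 °C, and hybridised to an Agilent human array of 52857 spots, per the labels. Groups of 3 control, 4 rapamycin, 4 nimotuzumab and 3 combination samples were read from the sample titles. The files carry 2 slides.

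The spot intensities in the scanner files had been extracted by Agilent Feature Extraction, version 10.5.1.1 per the file headers, while the submitters' processing notes name version 10.7. Processed intensities were background-subtracted and detrended over the array (spatial and multiplicative detrending), with surrogate values for dim spots, and mean spot and median background intensities were given as well, per the file headers. Flags for saturation, outlier spots, control spots and spots well above background came in the same files. The deposited table of the series holds log2 values, and comparison with the scanner files showed that each column is log2 of the processed intensity minus a constant, with its 75th percentile at 0 and a median of −3.05 to −2.76. No spot was flagged as saturated. Outlier spots made up 0.0815% to 0.415% of each array, and the spike-ins gave a slope of 0.918 to 1.03 against their known amounts (r squared 0.986 to 0.998).

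Control and outlier spots were left out, spots of 1 probe were averaged, and log2 of the processed intensity minus the array's 75th percentile was used. Of 50238 probes, 28595 were named by accession, 2998 by symbol and 1176 by an older symbol in the reference table of GRCh38.p14, which was used for names only, and 17469 had no current symbol and stayed separate features that were never named. Among list members, NDUFA4, SPRR2A and FCGR1A were without a probe under a current name. For 9317 of 19614 symbols with more than 1 probe, the probe with the highest mean signal over all arrays stood for the gene, and the signs of the other probes were given where they differed. A feature was tested when it was well above background on at least 3 of the 14 arrays, which left 24652 features (16661 with a symbol). Of these, 264 lacked a value on some array and were left out of the list tests and the principal component analysis.

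The groups were compared by limma 3.58.1 in R 4.3.3 with a single model of 4 group means, residual degrees of freedom of 10 and an empirical Bayes prior of 3.12. Moderated tests were adjusted by the Benjamini-Hochberg method over all features, and a feature was called at an adjusted p under 0.05. The comparisons were rapamycin, nimotuzumab and the combination against control, the combination against each single agent, and the interaction. All 35 gene lists were tested by camera with a correlation between genes preset at 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and by fry. Their counts were also taken with p adjusted over the list alone, by limma in the same model. Every p printed for a gene or list is adjusted, of limma or camera. Tables were read with data.table (version 1.17.8) and pandas 2.3.3, with numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

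Genes were named by a rule. For the comparisons against control, the 8 called genes with the largest log2 difference in each direction whose groups did not overlap were named, and for the other comparisons and the interaction 5. Where fewer than 3 genes of a direction passed, the 3 with the smallest p were named as not passing. For up to 8 called lists per comparison with the smallest p, the 3 members with the smallest p were named. EGFR, MTOR and FKBP1A were named throughout. XIST, Y-linked genes, LOC names, uncharacterised transcripts and genes without a current name were passed over, and ribosomal protein, HLA and keratin genes, whose families are near-identical, were named with a caution on cross-hybridisation. A few genes that the rule names are not given. Genes outside the rule are marked as chosen after their values were seen.

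The tests were run on simulated data of 24388 features, 100 changed by a log2 of 1 and 100 by 2. Recovery was 36% and 89% for rapamycin against control, 37% and 90% for nimotuzumab against control, 43% and 81% for the combination against control, and 33% and 87% for the combination against nimotuzumab, with 3.10%, 4.51%, 8.15% and 3.23% of the calls false. The 1 changed list was found and 0 others called each time, but correlated genes were not simulated.

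The alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, the series table, no filter on dim probes, a filter that asked for all 14 arrays, the mean of a gene's probes, the trend and robust options of limma, only the arrays of the groups compared, slide as a block with a single rapamycin effect, the replicate number as a block, each array left out in turn, and a fold of at least 2. Tumour sizes and protein levels were not in the files.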

Results

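Gene expression was measured in 14 tumours grown in mice from A431, a human epidermoid carcinoma line known for its high level of EGFR, the epidermal growth factor receptor. The samples fell into 4 groups: 3 untreated controls, 4 tumours treated with rapamycin, 4 treated with nimotuzumab and 3 treated with both agents, called the combination here. Rapamycin binds FKBP12, the product of FKBP1A, and inhibits the kinase mTOR, and nimotuzumab is an antibody against EGFR. Tumours were taken on day 18, 2 hours after the last dose. The labels do not state whether each sample came from a separate mouse, so the p-values below measure the spread between samples.

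Each sample was hybridised to its own 1-colour human array, and the number of arrays limits the precision of every value. The control and rapamycin arrays lay on slide 1 and the nimotuzumab and combination arrays on slide 2. The 75th percentile of the log2 signal ranged from 8.33 (rapamycin 1) to 9.45 (combination 1), and 62.1% (rapamycin 1) to 74.0% of the spots were well above background. In a principal component analysis the first component took 32.9% of the variance and separated the 7 arrays of slide 1 from the 7 arrays of slide 2. Combination 1 stood apart from all other arrays on the second component, which took 16.5%, and its deviations from its group mean had an SD of 0.56 where the other arrays had 0.28 to 0.43. Values below are log2 differences between group means ± standard error (SE) for 3 control, 4 rapamycin, 4 nimotuzumab and 3 combination arrays. Gene lists and the rule for naming genes had been fixed before the data were examined, and the p-values of lists are those of camera.

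**Figure D1:**
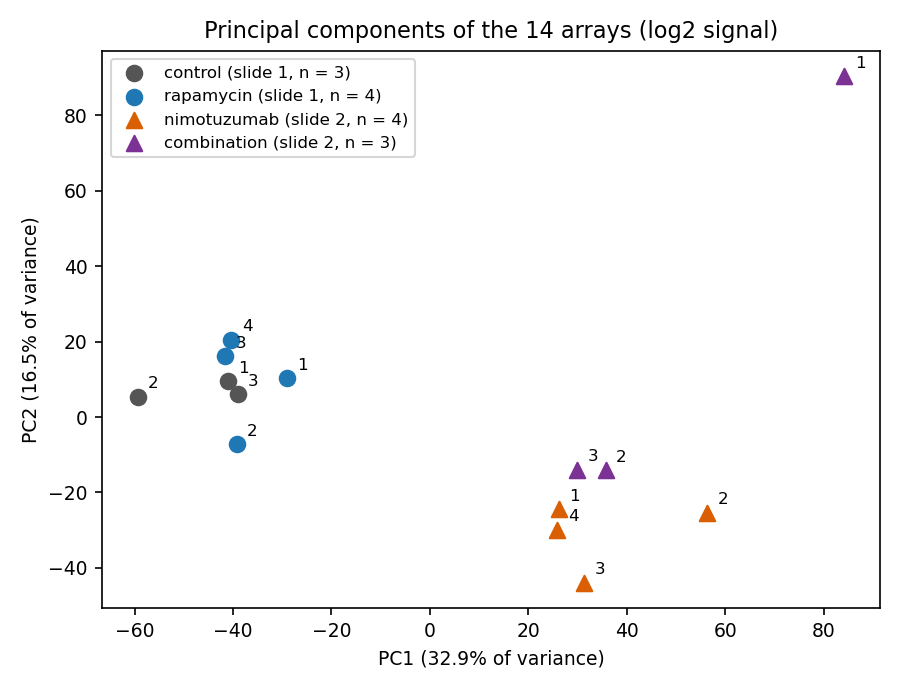
Principal components 1 and 2 of the log2 values of the tested features with a value on every array, 1 point per array, by treatment group and slide. The control and rapamycin arrays lie at −59.4 to −29.1 on the first component and the nimotuzumab and combination arrays at 25.9 to 84.2, with combination 1 at 90.4 on the second.

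Rapamycin alone was compared with control within slide 1, which addresses the effect of mTOR inhibition on otherwise untreated tumours. Control lay in row 1 of the slide and rapamycin in row 2, so row and treatment cannot be told apart. Transcripts of ribosomal proteins rose as a group by a small amount, with 74 of 76 members above 0 and a median of 0.16 (adjusted p = 1.05e-09, and adjusted p = 0.58 with an estimated correlation). The median deviation of these genes was 0.30, 0.19 and 0.12 on rapamycin 1, 2 and 3 but −0.13 on rapamycin 4, below the −0.10 to −0.01 of the controls. The 75th percentile of the signal on the same rapamycin arrays was 8.33, 8.69, 8.85 and 8.99. Genes of the hypoxia response fell (20 of 20 members below 0, median −0.35, adjusted p = 1.02e-05, and adjusted p = 0.463 with an estimated correlation). Glycolysis genes (18 of 19 below 0, median −0.30, adjusted p = 1.33e-05) and fibroblast and stroma markers (17 of 21, median −0.47, p = 1.86e-05) fell as well, each with an adjusted p = 0.444 with an estimated correlation. Without control 1 the median was −0.17 for hypoxia, −0.15 for glycolysis and −0.25 for fibroblast genes, and hypoxia lay at −0.70 without control 2 and −0.57 without rapamycin 1. Ribosomal proteins lay at 0.10 without rapamycin 1 and 0.25 without rapamycin 4. No single gene passed the test in this comparison.

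Smaller downward shifts passed for the integrated stress response (25 of 31 members below 0, median −0.16, adjusted p = 0.00013), ribosome biogenesis (29 of 32, median −0.17, p = 0.000149) and basal keratinocyte genes (15 of 17, median −0.24, p = 0.000412), all at an adjusted p = 0.444 with an estimated correlation. Epithelial-mesenchymal transition (14 of 19, median −0.23, adjusted p = 0.0167) and MAPK output (12 of 19, median −0.10, p = 0.0395) fell, again at an adjusted p = 0.444 with an estimated correlation. G1/S and DNA replication (27 of 32 below 0, median −0.18, adjusted p = 0.000565) and keratinocyte differentiation (25 of 37, median −0.07, p = 0.0395) also fell, with an adjusted p = 0.58 and 0.582 with an estimated correlation. Without control 1 the median was −0.13 for basal keratinocyte genes, −0.06 for epithelial-mesenchymal transition and 0.00 for MAPK output. Without control 2 it was −0.04 for the integrated stress response and G1/S, −0.08 for ribosome biogenesis and −0.31 for MAPK output. Without rapamycin 1 it was −0.11 for G1/S and −0.23 for MAPK output, and without rapamycin 2 it was −0.15 for basal keratinocyte genes. MAPK output lay at −0.005 without rapamycin 2 and −0.07 without rapamycin 3. Keratinocyte differentiation lay at −0.19 to −0.02 without control 2, control 3, rapamycin 1, rapamycin 3 or rapamycin 4.

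Among the ribosomal protein genes, RPS16 differed by 0.31 ± 0.12, RPL28 by 0.32 ± 0.13 and RPL41 by 0.33 ± 0.14. Only 1 of the 5 other RPL28 probes had the same sign. Probes for ribosomal proteins, HLA genes and keratins can cross-hybridise within their families. The angiogenic factor gene VEGFA differed by −0.87 ± 0.39, the collagen crosslinking enzyme LOX by −0.94 ± 0.45 (−0.20 with the 3 of 4 rapamycin arrays not well above background at their lower bound) and STC2 by −0.85 ± 0.46. The glycolytic genes ALDOC, GAPDH and PFKP differed by −0.53 ± 0.21, −0.63 ± 0.26 and −0.36 ± 0.18. The collagen genes COL5A1, COL1A1 and COL1A2 differed by −0.84 ± 0.22, −0.72 ± 0.29 and −0.73 ± 0.32. In the integrated stress response, the cystine transporter SLC7A11 differed by −0.99 ± 0.32, PYCR1 by −0.35 ± 0.15 and the serine synthesis gene PSAT1 by −0.63 ± 0.28. Ribosome biogenesis was represented by GNL3 (−0.34 ± 0.14), WDR43 (−0.30 ± 0.15) and LYAR (−0.31 ± 0.22). The basal keratinocyte genes were represented by CDH3 (−0.32 ± 0.13), CAV1 (−0.38 ± 0.19) and KRT5 (−0.38 ± 0.24). For G1/S these were ORC1 (−0.42 ± 0.21), CHAF1A (−0.27 ± 0.14) and MCM6 (−0.42 ± 0.23). None of these genes passed the test alone. Without control 1 PFKP lay at −0.19, without control 2 PSAT1 at −0.21 and WDR43 at −0.20, without control 3 KRT5 at −0.58, and without rapamycin 2 CAV1 at −0.25 and LYAR at −0.20.

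The smallest p-values in rapamycin against control belonged to FRAT1 (1.51 ± 0.20, adjusted p = 0.0772) and GPAT3 (1.47 ± 0.27, 0.576). On the lower side they belonged to ARHGAP25 (−1.09 ± 0.19), QPRT (−1.55 ± 0.27) and ADGRG2 (−2.19 ± 0.42), which was well above background on only 1 of the 4 rapamycin arrays. The targets differed by −0.18 ± 0.23 for EGFR, 0.22 ± 0.20 for MTOR and 0.17 ± 0.20 for FKBP1A.

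The limma test called 0 of 24652 features, with 1162 at an unadjusted p under 0.05 where 1232.6 are expected by chance, and the trend and robust options called 1. The count was 1 without nimotuzumab 2, without combination 1 or without combination 2. Adjusted over the list alone, 1 fibroblast gene, 1 gene of the MAPK output list and 1 of the EGFR ligands and receptors were lower and 2 genes of the FOXO list were higher. List calls ended without control 2 for the integrated stress response (adjusted p = 0.0898), ribosome biogenesis (0.0771) and G1/S (0.458). Without rapamycin 1 they ended for G1/S (adjusted p = 0.116) and epithelial-mesenchymal transition (0.0551), which also lost its call without control 1 (0.122) or rapamycin 2 (0.257). MAPK output lost its call without control 1, control 3, rapamycin 2 or rapamycin 3 (adjusted p = 0.0801 to 0.478). Keratinocyte differentiation lost its call without control 1, control 3, rapamycin 3, rapamycin 4 or combination 1 (adjusted p = 0.0592 to 0.457). MAPK output also lost its call with normexp background correction (adjusted p = 0.0549), the mean of all probes (0.0757) or only the arrays compared (0.0611), and keratinocyte differentiation with the mean of all probes (0.0757) or only the arrays compared (0.126).

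With slide as a block and 1 rapamycin effect over both slides, 3 features passed: GPAT3 and FRAT1 rose (adjusted p = 0.033 for both) and ARHGAP25 fell (adjusted p = 0.0411). In that fit ribosomal proteins rose (median 0.21, adjusted p = 3.42e-12) and fibroblast markers fell (median −0.48, adjusted p = 2.76e-10). Falls were also found for ribosome biogenesis (−0.14, adjusted p = 3.62e-05), the integrated stress response (−0.10, 0.000991), glycolysis (−0.14, 0.0104) and epithelial-mesenchymal transition (−0.10, 0.0104). Hypoxia (adjusted p = 0.462), basal keratinocyte (0.581), G1/S (0.101), MAPK output (0.153) and keratinocyte differentiation genes (0.0557) no longer passed. An estimated correlation was not tried in that fit, where row and rapamycin cannot be told apart.

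**Figure D2:**
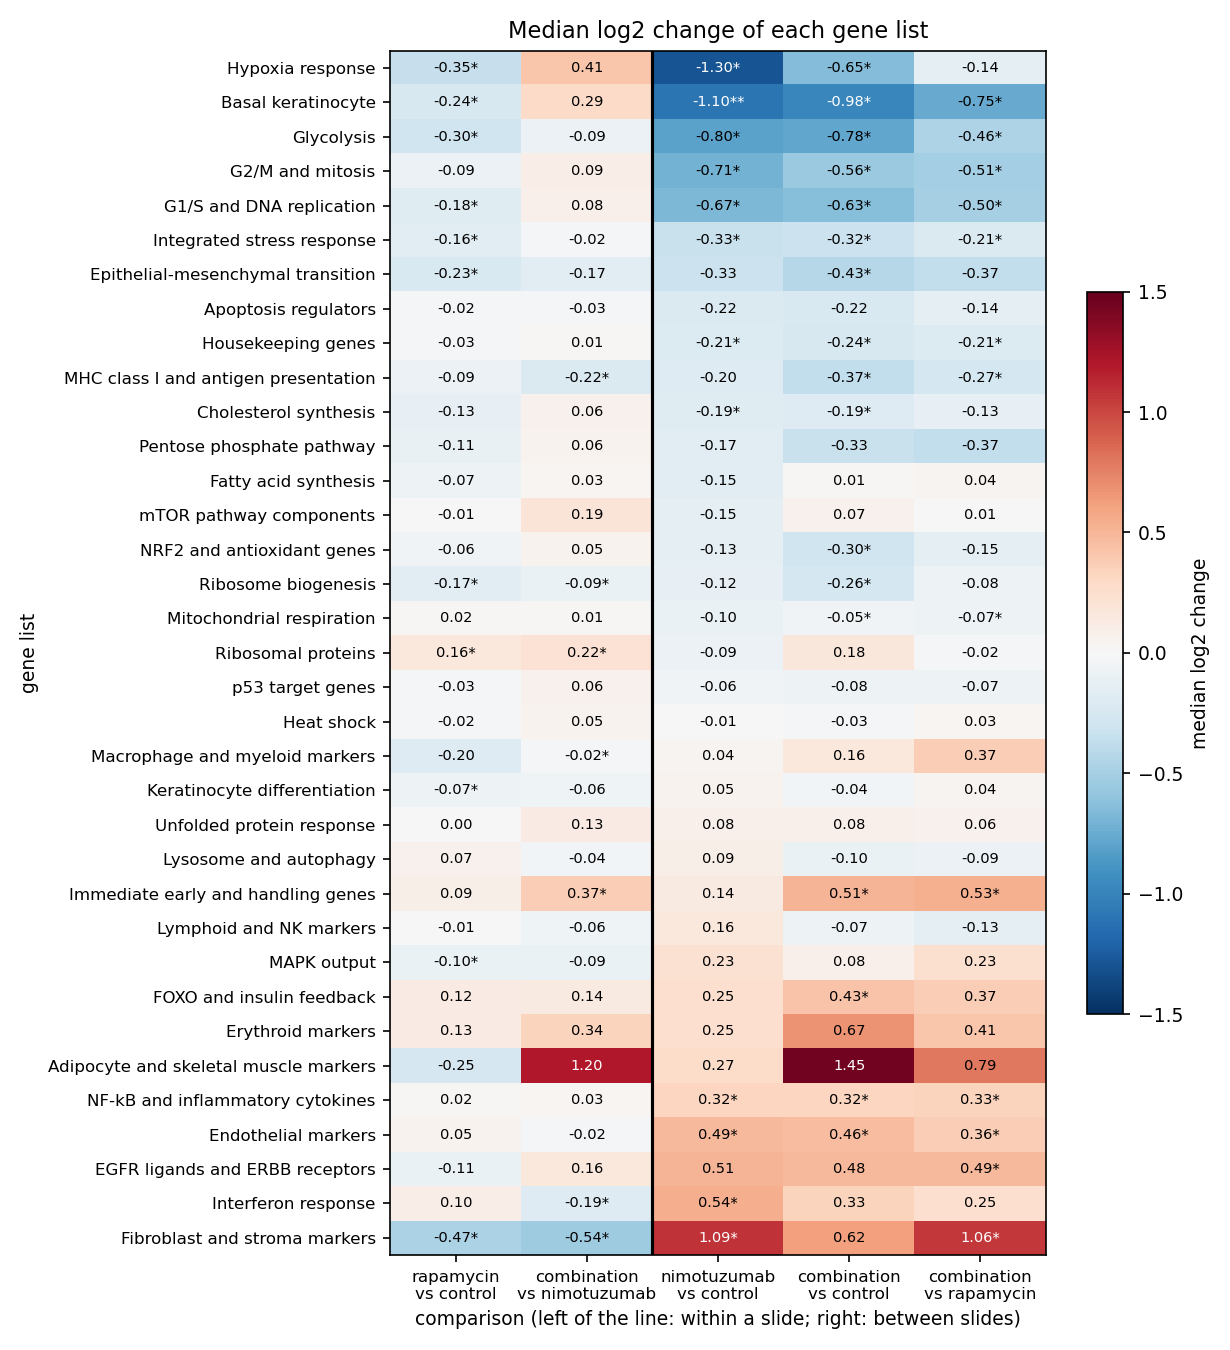
Median log2 difference of the tested members of each of the 35 gene lists (y axis) in 5 comparisons (x axis), with a black line between comparisons within a slide, on the left, and between slides, on the right. One star marks a camera adjusted p under 0.05 with the preset correlation and a pair of stars one that also held with an estimated correlation, as for the basal keratinocyte list at −1.10 in nimotuzumab against control.

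Nimotuzumab alone was compared with control, which addresses the effect of EGFR blockade on its own. Genes of the basal keratinocyte layer fell together: 15 of 17 members were lower and 0 higher, with a median of −1.10 (adjusted p = 1.92e-15, and adjusted p = 0.036 with an estimated correlation). Genes of mitosis (14 of 31 lower, median −0.71, adjusted p = 8.99e-13) and DNA replication (13 of 32 lower, median −0.67, p = 4.86e-11) fell, with an adjusted p = 0.279 and 0.312 with an estimated correlation. Genes of glycolysis (11 of 19 lower, median −0.80, adjusted p = 2.88e-09) and the hypoxia response (8 of 20 lower, median −1.30, p = 1.8e-05) fell, with an adjusted p = 0.166 and 0.48 with an estimated correlation. Collagen and other stromal genes rose (11 of 21 higher and 1 lower, median 1.09, adjusted p = 2.26e-06, and adjusted p = 0.166 with an estimated correlation).

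Interferon-stimulated genes (9 of 36 higher, median 0.54, adjusted p = 1.77e-05) and endothelial markers (5 of 15 higher, median 0.49, p = 0.00505) also rose in nimotuzumab-treated tumours, with an adjusted p = 0.455 and 0.312 with an estimated correlation. Adjusted over the list alone, 16 basal keratinocyte, 22 mitosis, 19 G1/S, 13 glycolysis, 10 hypoxia and 3 fibroblast genes were lower, and 13 fibroblast, 14 interferon, 5 endothelial and 1 hypoxia gene were higher. Slide and treatment cannot be told apart for any of these differences. The probes are human and the files do not separate mouse from human transcripts.

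In the basal list, P-cadherin CDH3 fell by 1.34 ± 0.13 (adjusted p = 0.000145), caveolin-1 CAV1 by 1.68 ± 0.19 (0.000235) and integrin alpha 6 ITGA6 by 1.39 ± 0.16 (0.000306). Of the mitotic genes, the kinase gene PLK1 fell by 0.88 ± 0.16 (adjusted p = 0.00443), ANLN by 1.12 ± 0.24 (0.00983) and CDC20 by 1.20 ± 0.26 (0.0119). Of the replication genes, thymidine kinase TK1 fell by 1.24 ± 0.19 (adjusted p = 0.00141), UHRF1 by 0.82 ± 0.14 (0.00324) and MCM6 by 1.23 ± 0.23 (0.00469). Slide and treatment cannot be told apart for these genes.

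The glycolytic genes ALDOC (−1.14 ± 0.21, adjusted p = 0.00454) and GPI (−1.10 ± 0.22, 0.00639) and the lactate transporter SLC16A3 (−1.59 ± 0.30, 0.00546) fell. So did the hypoxia genes P4HA2 (−1.5 ± 0.18, adjusted p = 0.000402), ADM (−1.47 ± 0.28, 0.00575) and carbonic anhydrase CA9 (−3.24 ± 0.70, 0.0106). The small proteoglycan decorin DCN rose from 2.83 ± 0.65 to 6.20 ± 0.56 (group means ± SD, n = 3 and 4), by 3.36 ± 0.32 (adjusted p = 0.000127). The collagen genes COL5A2 and COL1A2 rose by 2.21 ± 0.23 (adjusted p = 0.00016) and 2.54 ± 0.32 (0.000449). Among interferon-stimulated genes IFIT3 rose by 1.23 ± 0.15 (adjusted p = 0.000327), IFI44L by 1.56 ± 0.28 (0.00366) and ISG15 by 1.07 ± 0.20 (0.00548). The endothelial receptors TIE1 (1.37 ± 0.21, adjusted p = 0.00139), ADGRL4 (1.99 ± 0.50, 0.0223) and ENG (1.02 ± 0.26, 0.0244) rose. None of the 2 other COL5A2 probes had the same sign, and its call ended with the mean of all probes (0.14, adjusted p = 0.78). The other UHRF1 probe also had the opposite sign, and with the mean of both UHRF1 fell short of a call (−0.27, adjusted p = 0.207). The call of ADGRL4, well above background on 1 of 3 control arrays, ended with quantile normalization (1.83, adjusted p = 0.0885). With normexp background correction, whose offset draws dim signals together, TIE1 (0.89) and ADGRL4 (0.63) moved by over 1.5 times and were still called. For these, slide and treatment cannot be told apart.

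The largest declines were in the keratin genes KRT2, from 5.12 ± 0.39 to 0.58 ± 0.64 (group means ± SD, a difference of −4.54 ± 0.68, adjusted p = 0.00131), and KRT76 (−4.21 ± 0.99, 0.0169). They were followed by the hormone gene PTHLH (−3.42 ± 0.41, adjusted p = 0.000375), surfactant protein D SFTPD (−3.38 ± 0.30, 9.3e-05) and CA9. Next came the interleukin 7 receptor IL7R (−3.20 ± 0.31, adjusted p = 0.000137), SCG5 (−3.19 ± 0.56, 0.00363) and PHGR1 (−3.09 ± 0.72, 0.016). IL7R was well above background on 1 (−2.86 with the others at the dimmest such level) and SCG5 on 3 of the 4 nimotuzumab arrays. With normexp, IL7R (−0.95), SCG5 (−1.25) and PHGR1 (−1.82) were smaller by over 1.5 times and were still called. Here too, slide and treatment cannot be told apart.

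Large increases in nimotuzumab against control were those of DCN, the alcohol dehydrogenase gene ADH1C (3.29 ± 0.35, adjusted p = 0.000181) and the immunoglobulin receptor PIGR (4.13 ± 1.06, 0.0253). PIGR was well above background on 1 of 3 control arrays, and differed by 2.88 with the others at the bound described next. A further 5 genes were well above background on 0 of 3 control arrays. For such genes a lower bound of the fold was taken, against the dimmest level called well above background on each control array, or the gene's own level where that was higher. These were TNMD, a tendon glycoprotein gene (at least 3.63-fold higher, adjusted p = 0.00659), the homeobox gene MEOX2 (at least 4.03-fold, 9.3e-05) and the proenkephalin gene PENK (at least 6.10-fold, 0.000938). The others were SEMA3D (at least 4.52-fold, adjusted p = 0.000847) and periostin POSTN (at least 4.14-fold, 0.00102). With normexp the log2 differences were smaller, though still called: 1.52 for PIGR, 1.08 for TNMD, 0.91 for MEOX2, 1.07 for PENK, 1.02 for SEMA3D and 0.94 for POSTN. EGFR differed by −0.54 ± 0.23 (adjusted p = 0.166), with 3 of its 5 other probes called lower. MTOR (0.25 ± 0.20, adjusted p = 0.486) and FKBP1A (−0.44 ± 0.20, 0.18) did not pass. In all of these, slide and treatment cannot be told apart.

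The limma test called 2800 features, 1620 higher and 1180 lower, which included 1207 higher and 909 lower genes with a symbol, and 6302 had an unadjusted p under 0.05. With each array scaled to its median the split was 1321 higher and 1418 lower. The count was 1456 without control 1, 1208 without control 2, 1855 without control 3, 1710 without nimotuzumab 2 and 1813 without nimotuzumab 3. Calls ended for PIGR without control 1, control 2, nimotuzumab 1 or nimotuzumab 2 (adjusted p = 0.0577 to 0.127), CA9 without control 1 (0.0569), and KRT76 (0.0846) and CDC20 (0.0655) without control 2. The call of PHGR1 ended without control 2 (adjusted p = 0.0793) or control 3 (0.0517). Calls also ended for ADGRL4 without control 2, control 3, nimotuzumab 1 or nimotuzumab 2 (0.0552 to 0.111), and ENG without any 1 control array, nimotuzumab 3 or nimotuzumab 4 (0.0597 to 0.0787). In these counts slide and treatment cannot be told apart.

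**Figure D3:**
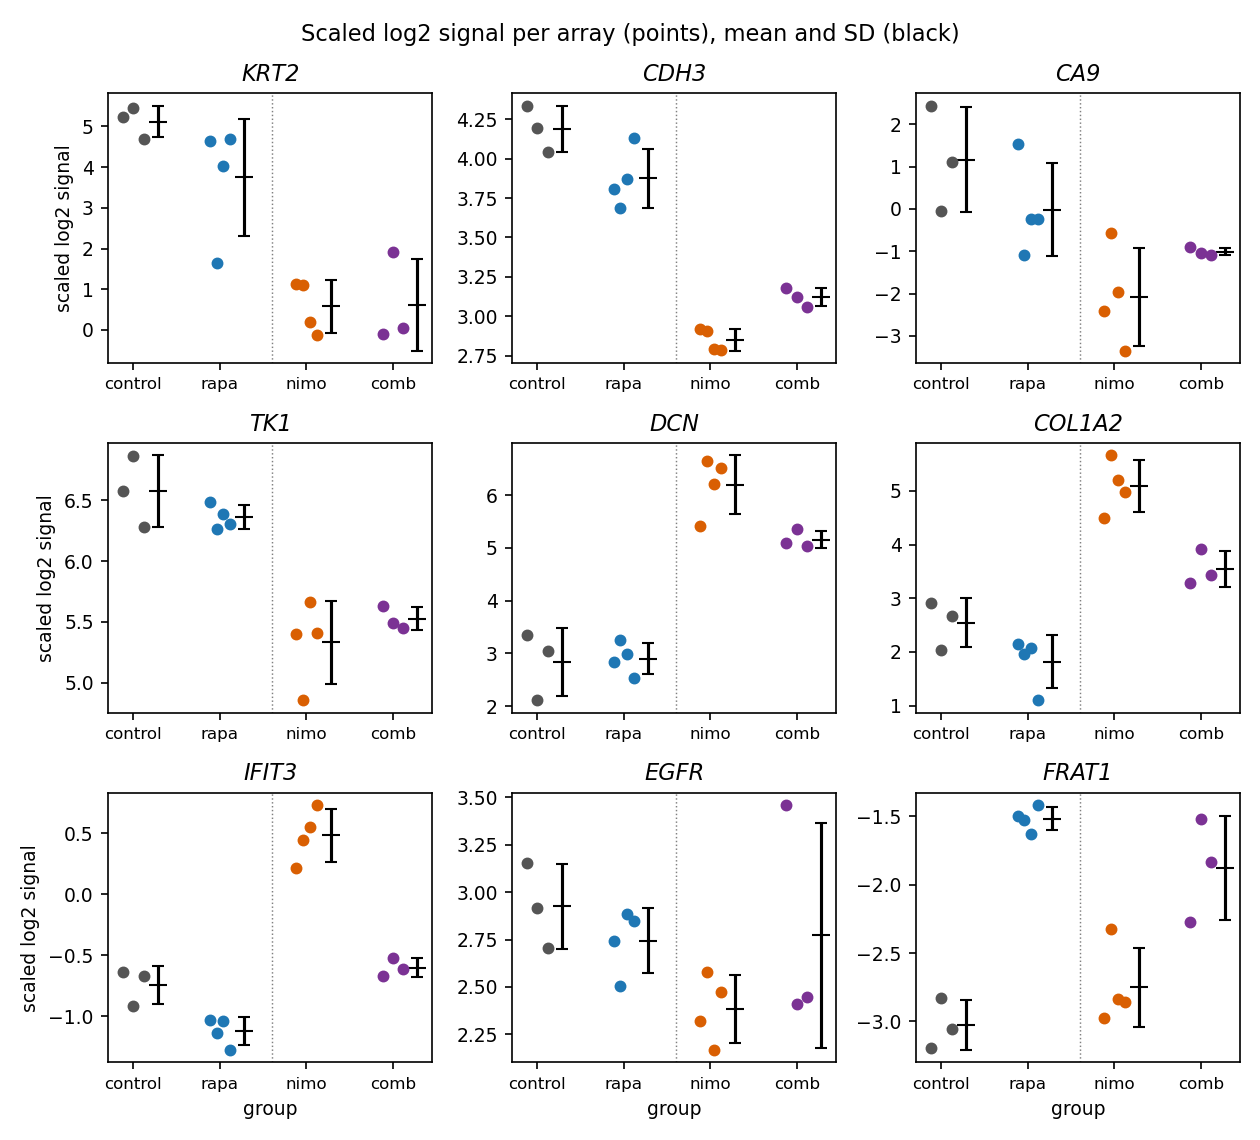
Scaled log2 signal of 9 genes on each array (points) by group, with the group mean and SD in black and a dotted line between the slides. KRT2 lies at a mean of 5.12 in control and 0.58 in nimotuzumab tumours, and DCN at 2.83 and 6.20.

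A further 4 lists with smaller shifts passed in nimotuzumab against control, where slide and treatment cannot be told apart. Genes of NF-kB and inflammatory cytokines rose (7 of 25 higher and 1 lower, 8 and 1 adjusted over the list alone, median 0.32, adjusted p = 0.013, and adjusted p = 0.312 with an estimated correlation). The integrated stress response fell (4 of 31 lower, 4 adjusted over the list alone, median −0.33, adjusted p = 0.00744, and adjusted p = 0.406 with an estimated correlation). Cholesterol synthesis genes fell (1 of 25 lower, 1 adjusted over the list alone, median −0.19, adjusted p = 0.0432, and adjusted p = 0.624 with an estimated correlation). Housekeeping genes also fell (3 of 20 lower, 7 lower and 1 higher adjusted over the list alone, median −0.21, adjusted p = 0.0422, and adjusted p = 0.455 with an estimated correlation). Without control 2 the calls ended for NF-kB (median 0.13, adjusted p = 0.0589), the integrated stress response (−0.22, 0.0809) and housekeeping genes (0.0834), which also lost theirs without nimotuzumab 2 (−0.14, 0.13) or nimotuzumab 4 (0.058). Cholesterol synthesis lost its call without control 1 (adjusted p = 0.128), rapamycin 1 (0.0501) or nimotuzumab 2 (0.177), and its median was −0.28 without control 3. Cholesterol synthesis and housekeeping genes also lost their calls with quantile normalization (adjusted p = 0.26 and 0.22), with the filter on all 14 arrays (0.0918 and 0.0872) or with only the arrays compared (0.053 and 0.0541), and cholesterol synthesis with the series table (0.0687).

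The combination was compared with control, which addresses the joint effect of both agents. Basal keratinocyte genes fell (11 of 17 lower and 0 higher, median −0.98, adjusted p = 8.98e-12, and adjusted p = 0.0897 with an estimated correlation). Genes of DNA replication (15 of 32 lower and 1 higher, median −0.63, adjusted p = 2.00e-09) and mitosis (12 of 31 lower, median −0.56, p = 3.33e-09) fell, each with an adjusted p = 0.325 with an estimated correlation. Glycolysis genes fell (8 of 19 lower, median −0.78, adjusted p = 3.33e-09, and adjusted p = 0.208 with an estimated correlation). Immediate early genes, which growth factors and tissue handling induce, rose (8 of 21 higher, median 0.51, and 0.30 without combination 1, adjusted p = 0.017, and adjusted p = 0.472 with an estimated correlation).

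The integrated stress response (8 of 31 lower, median −0.32, adjusted p = 0.000155) and ribosome biogenesis (3 of 32 lower, median −0.26, p = 0.00062) also fell in combination-treated tumours, with an adjusted p = 0.325 and 0.332 with an estimated correlation. Hypoxia genes (1 of 20 lower, median −0.65, adjusted p = 0.00549) and antigen presentation genes (3 of 20 lower and 2 higher, median −0.37, p = 0.00693) fell as groups, with an adjusted p = 0.472 and 0.325 with an estimated correlation. The hypoxia median was −1.02 without combination 1, −0.40 without combination 3 and −0.32 without control 1. Without control 2 that of the integrated stress response was −0.20 and of ribosome biogenesis −0.13. The fibroblast list, with a median of 0.62 and 6 of 21 genes higher and 3 lower, did not pass (adjusted p = 0.144). Adjusted over the list alone, 14 basal keratinocyte, 20 G1/S, 14 glycolysis, 12 mitosis, 9 integrated stress response, 5 ribosome biogenesis, 1 hypoxia, 7 antigen presentation and 4 fibroblast genes were lower, and 9 immediate early and 8 fibroblast genes were higher. The groups lay on different slides and rows, and slide and treatment cannot be told apart.

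CDH3, ITGA6 and CAV1 fell by 1.07 ± 0.14 (adjusted p = 0.00227), 1.13 ± 0.17 (0.00357) and 1.23 ± 0.20 (0.00476). The replication genes GINS2, TK1 and ORC1 fell by 1.19 ± 0.22 (adjusted p = 0.00743), 1.05 ± 0.20 (0.00933) and 1.07 ± 0.22 (0.0127). The mitotic genes CDC20, BIRC5 and FOXM1 fell by 1.72 ± 0.28 (adjusted p = 0.00476), 0.94 ± 0.21 (0.0162) and 0.92 ± 0.21 (0.0186). The glycolytic genes ALDOC, TPI1 and ENO1 fell by 1.24 ± 0.22 (adjusted p = 0.00721), 0.93 ± 0.18 (0.00861) and 1.45 ± 0.29 (0.0112). In the integrated stress response, PYCR1, PHGDH and SLC3A2 fell by 0.74 ± 0.16 (adjusted p = 0.0163), 0.93 ± 0.22 (0.0214) and 0.92 ± 0.24 (0.0291). The ribosome biogenesis genes NOP2, NOP14 and WDR43 fell by 1.11 ± 0.27 (adjusted p = 0.0249), 0.90 ± 0.22 (0.0256) and 0.58 ± 0.16 (0.0352). Of the hypoxia genes only P4HA2 passed (−1.08 ± 0.20, adjusted p = 0.00728), with VEGFA at −1.22 ± 0.42 (0.0726) and LOX at 1.49 ± 0.48 (0.06). Without combination 1 NOP2 lay at −0.73 and LOX at 0.90. In the antigen presentation list the class II genes HLA-DMA (1.37 ± 0.26, adjusted p = 0.00911) and CD74 (1.85 ± 0.42, 0.0192) rose while the immunoproteasome gene PSMB8 fell (−0.72 ± 0.20, 0.0399). The other HLA-DMA probe had the opposite sign, and the call ended with the mean of both (0.50, adjusted p = 0.202). With normexp the calls ended for ORC1 (−0.38, adjusted p = 0.185) and NOP14 (−0.43, 0.117), while CD74 (0.76) and HLA-DMA (0.90) were smaller by over 1.5 times and were still called.

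The largest declines were again in keratin genes, KRT2 (−4.50 ± 0.73, adjusted p = 0.00469), KRT76 (−4.07 ± 1.06, 0.0307), KRT3 (−3.16 ± 0.52, 0.00476) and KRT72 (−3.05 ± 0.44, 0.0028). They were joined by KANK4 (−3.35 ± 0.35, adjusted p = 0.000893), ANKDD1A (−3.25 ± 0.62, 0.00931), SFTPD (−3.01 ± 0.32, 0.000971) and PHGR1 (−2.89 ± 0.77, 0.0328). Large increases were those of PSCA (3.29 ± 0.82, adjusted p = 0.0254), MSMB (3.09 ± 0.41, 0.00227), GCM2 (3.47 ± 0.59, 0.00587) and PIGR (3.82 ± 1.14, 0.0472). GCM2 was well above background on 2 and PIGR on 1 of 3 control arrays, and they differed by 3.16 and 2.57 with the others at the bound. GPR85 (at least 2.59-fold higher, adjusted p = 0.00258) and CLIC5 (at least 3.50-fold, 0.0391) were well above background on 0 of 3 control arrays. So were NPY1R (at least 2.20-fold, adjusted p = 0.00165) and MEOX2 (at least 3.66-fold, 0.000893). With normexp the calls ended for PIGR (1.24, adjusted p = 0.0509) and CLIC5 (0.79, 0.0542). GCM2 (1.42), GPR85 (0.77), NPY1R (0.61), MEOX2 (0.77), KRT72 (−1.82) and PHGR1 (−1.73) were smaller by over 1.5 times with normexp and were still called. EGFR (−0.15 ± 0.25, adjusted p = 0.696), MTOR (−0.04 ± 0.22) and FKBP1A (−0.49 ± 0.21, 0.132) did not pass. Without combination 1 they lay at −0.50, 0.21 and −0.21, and EGFR lay at 0.03 without combination 2 and 0.01 without combination 3. For these genes, slide and treatment cannot be told apart.

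In the combination against control the limma test called 2743 features, 1723 higher and 1020 lower (1209 and 810 genes with a symbol), with 7716 at an unadjusted p under 0.05. The median of all features was 0.12 above control, and with median scaling it was −0.06 and the split turned to 1049 higher and 1919 lower, against 1296 and 1184 with quantile normalization. The count of the combination against control was 1077 without control 1, 661 without control 2, 1671 without control 3 and 1754 without combination 1, the array that stood apart. In these counts slide and treatment cannot be told apart.

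For the combination against control, gene calls ended without control 2 for PIGR, CLIC5, PSCA, KRT76, PHGR1, PYCR1, PHGDH, NOP2, NOP14, WDR43, PSMB8, ORC1, ENO1, BIRC5, FOXM1, SLC3A2 and CD74 (adjusted p = 0.0536 to 0.176). Without control 1 they ended for the first 11 of these (adjusted p = 0.0516 to 0.141), and without control 3 for CLIC5, KRT76, PHGR1, NOP14, WDR43 and SLC3A2 (0.0527 to 0.101). Without combination 1 they ended for PIGR, CLIC5, PSCA, KRT76, PHGR1, PHGDH, NOP14, WDR43, PSMB8, SLC3A2 and CD74 (adjusted p = 0.0511 to 0.1). Without combination 2 they ended for PIGR, CLIC5, PSCA and PSMB8 (adjusted p = 0.0558 to 0.103), and without combination 3 for PIGR, CLIC5, KRT76, PHGR1, WDR43 and PSMB8 (0.054 to 0.0776). PIGR and PSMB8 each lost their call on removal of any 1 of 10 arrays, up to an adjusted p = 0.176 and 0.156. PIGR also lost its call with the trend and robust options (adjusted p = 0.0604), no filter (0.0634) or quantile normalization (0.0706), CLIC5 with no filter (0.0534) or quantile normalization (0.056), PSCA with the mean of all probes (0.0577), and PSMB8 (0.056) and WDR43 (0.0506) with no filter. With only the arrays compared, calls ended for 25 genes, all called ones named in this comparison but CDH3, ITGA6, CAV1, KRT2, KRT3, KRT72, KANK4, SFTPD, GCM2, MSMB, CLIC5, NPY1R and MEOX2 (adjusted p = 0.0511 to 0.143). The hypoxia call ended without control 1 (adjusted p = 0.0541), and the immediate early call without control 2 (0.0907) or combination 1 (0.0574).

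A further 8 lists passed for the combination against control, where slide and treatment cannot be told apart. Endothelial markers (2 of 15 higher, 5 adjusted over the list alone, median 0.46, adjusted p = 0.0264) and NF-kB genes (6 of 25 higher and 1 lower, 7 and 1 adjusted over the list alone, median 0.32, p = 0.0264) rose, each at an adjusted p = 0.332 with an estimated correlation. Genes of FOXO and insulin feedback also rose (5 of 20 higher and 1 lower, 8 and 1 adjusted over the list alone, median 0.43, adjusted p = 0.0182), again at an adjusted p = 0.332 with an estimated correlation. Cholesterol synthesis (3 of 25 lower, 4 adjusted over the list alone, median −0.19, adjusted p = 0.00929) and NRF2 and antioxidant genes (1 of 23 lower, median −0.30, p = 0.0129) fell, with an adjusted p = 0.465 and 0.325 with an estimated correlation. Housekeeping genes (4 of 20 lower, median −0.24, adjusted p = 0.017) and epithelial-mesenchymal transition genes (3 of 19 lower and 2 higher, 7 and 2 adjusted over the list alone, median −0.43, p = 0.0222) fell, each with an adjusted p = 0.332 with an estimated correlation. Mitochondrial respiration fell (2 of 25 lower, median −0.05, adjusted p = 0.0378, and adjusted p = 0.56 with an estimated correlation). Without combination 1 the median was 0.15 for NF-kB, −0.34 for cholesterol synthesis and −0.16 for mitochondrial respiration, without combination 2 −0.06 and 0.09 for the last pair, and without combination 3 −0.26 for epithelial-mesenchymal transition. Mitochondrial respiration lay at −0.01 without control 2 and −0.13 without control 3. Single arrays ended the calls of endothelial markers (without control 2, combination 2 or combination 3, adjusted p = 0.057 to 0.0897), NF-kB (without control 2, 0.0907), and cholesterol synthesis (without combination 2, 0.197). They also ended those of NRF2 (without combination 2, adjusted p = 0.0626), epithelial-mesenchymal transition (without combination 3, 0.0696) and mitochondrial respiration (without control 2, 0.136, or combination 2, 0.472). With the mean of all probes the calls ended for endothelial markers, FOXO and mitochondrial respiration (adjusted p = 0.051 for each), epithelial-mesenchymal transition (0.0632) and immediate early genes (0.0595, and 0.0711 with only the arrays compared). With quantile normalization they ended for endothelial markers (adjusted p = 0.0863), cholesterol synthesis and epithelial-mesenchymal transition (0.0521 for both) and mitochondrial respiration (0.27). With the filter on all 14 arrays they ended for endothelial markers (adjusted p = 0.0658), epithelial-mesenchymal transition (0.0549, and 0.0644 with median scaling), mitochondrial respiration (0.0898) and NF-kB (0.0524).

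The combination was compared with nimotuzumab within slide 2, which addresses what rapamycin adds to nimotuzumab. Nimotuzumab lay in row 1 of the slide and the combination in row 2, so row and rapamycin cannot be told apart. Fibroblast and stroma markers fell as a group, with 19 of 21 members below 0 and a median of −0.54 (adjusted p = 2.15e-08, and adjusted p = 0.173 with an estimated correlation). Ribosomal protein genes rose as a group, with 72 of 76 members above 0 and a median of 0.22 (adjusted p = 9.01e-07, and adjusted p = 0.771 with an estimated correlation). Interferon-stimulated genes (26 of 36 below 0, median −0.19, adjusted p = 0.000103) and antigen presentation genes (17 of 20, median −0.22, p = 0.000321) fell, with an adjusted p = 0.669 and 0.376 with an estimated correlation. Immediate early genes (18 of 21 above 0, median 0.37, adjusted p = 0.00888) rose, with an adjusted p = 0.669 with an estimated correlation. Ribosome biogenesis (20 of 32 below 0, median −0.09, adjusted p = 0.00533) and macrophage markers (10 of 20 below 0, median −0.02, mean −0.16, p = 0.0446) fell, each with an adjusted p = 0.669 with an estimated correlation. The median was 0.10 for immediate early genes without combination 1, −0.11 for interferon genes without nimotuzumab 2, and −0.05, −0.17 and −0.06 for ribosome biogenesis without nimotuzumab 1, nimotuzumab 2 and combination 2. That of macrophage markers moved by over 1.5 times without any 1 array of slide 2, from −0.28 without combination 2 to 0.10 without nimotuzumab 2. No single gene passed the test.

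COL1A2 differed by −1.55 ± 0.32 (adjusted p = 0.137), COL5A2 by −1.09 ± 0.23 and the matrix protease gene MMP2 by −1.81 ± 0.40 (0.165). RPS23, RPS28 and RPL26 differed by 0.57 ± 0.16, 0.48 ± 0.14 and 0.58 ± 0.19. The other RPS28 probe had the opposite sign. IFIT3 differed by −1.09 ± 0.15 (adjusted p = 0.0865), OAS1 by −0.73 ± 0.19 and STAT2 by −0.51 ± 0.18. In antigen presentation, HLA-E differed by −0.53 ± 0.21, CD74 by −1.0 ± 0.40 and NLRC5 by −0.53 ± 0.22. The ribosome biogenesis genes NOP2, RRP12 and RRP9 differed by −0.76 ± 0.26, −0.66 ± 0.23 and −0.43 ± 0.16. Of the immediate early genes, JUNB differed by 0.66 ± 0.12 (adjusted p = 0.137, its other probe with the opposite sign), GADD45B by 0.50 ± 0.14 and IER2 by 0.53 ± 0.15. The myeloid genes C1QB, LYZ and CD14 differed by −1.01 ± 0.26, −0.91 ± 0.32 and −0.41 ± 0.16. Beside these, the smallest p-values were those of the olfactory receptor gene OR52H1 (at least 1.79-fold higher, on 2 of 3 combination and 0 of 4 nimotuzumab arrays, adjusted p = 0.0893) and GPAT3 (1.42 ± 0.27, 0.137). On the lower side they were those of the CTP synthase gene CTPS2 (−1.10 ± 0.16, adjusted p = 0.0865) and LIMD2 (−1.54 ± 0.25, 0.112). EGFR differed by 0.39 ± 0.23 (adjusted p = 0.432), MTOR by −0.29 ± 0.20 and FKBP1A by −0.05 ± 0.20. Without combination 1 the values were 0.36 for RPS23, 0.33 for RPL26, −0.48 for OAS1, −0.34 for NLRC5, −0.26 for HLA-E and RRP9, −0.38 for NOP2 and RRP12, 0.04 for EGFR, −0.04 for MTOR and 0.22 for FKBP1A.

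The limma test called 0 features for the combination against nimotuzumab, with 3661 at an unadjusted p under 0.05 and 9 called with the trend and robust options. It called 8 without nimotuzumab 1, 7 without combination 3 and 1 without rapamycin 3. Adjusted over the list alone, 7 fibroblast, 2 interferon and 1 macrophage gene were lower and 4 immediate early genes were higher. The immediate early call ended without combination 1 (adjusted p = 0.176), ribosome biogenesis without nimotuzumab 1 (0.0971) or combination 2 (0.07). The macrophage call ended without rapamycin 1, rapamycin 4, nimotuzumab 2, nimotuzumab 3, combination 2 or combination 3 (adjusted p = 0.0508 to 0.197). The immediate early call ended too with the mean of all probes (adjusted p = 0.276), and the macrophage call with median scaling (0.0905) or no filter (0.0751). With slide as a block and 1 rapamycin effect over both slides the interferon call ended (adjusted p = 0.0617). In that fit antigen presentation (median −0.16, adjusted p = 0.00185), immediate early genes (0.18, 0.0104) and macrophage markers (−0.09, 0.0186) still passed.

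**Figure D4:**
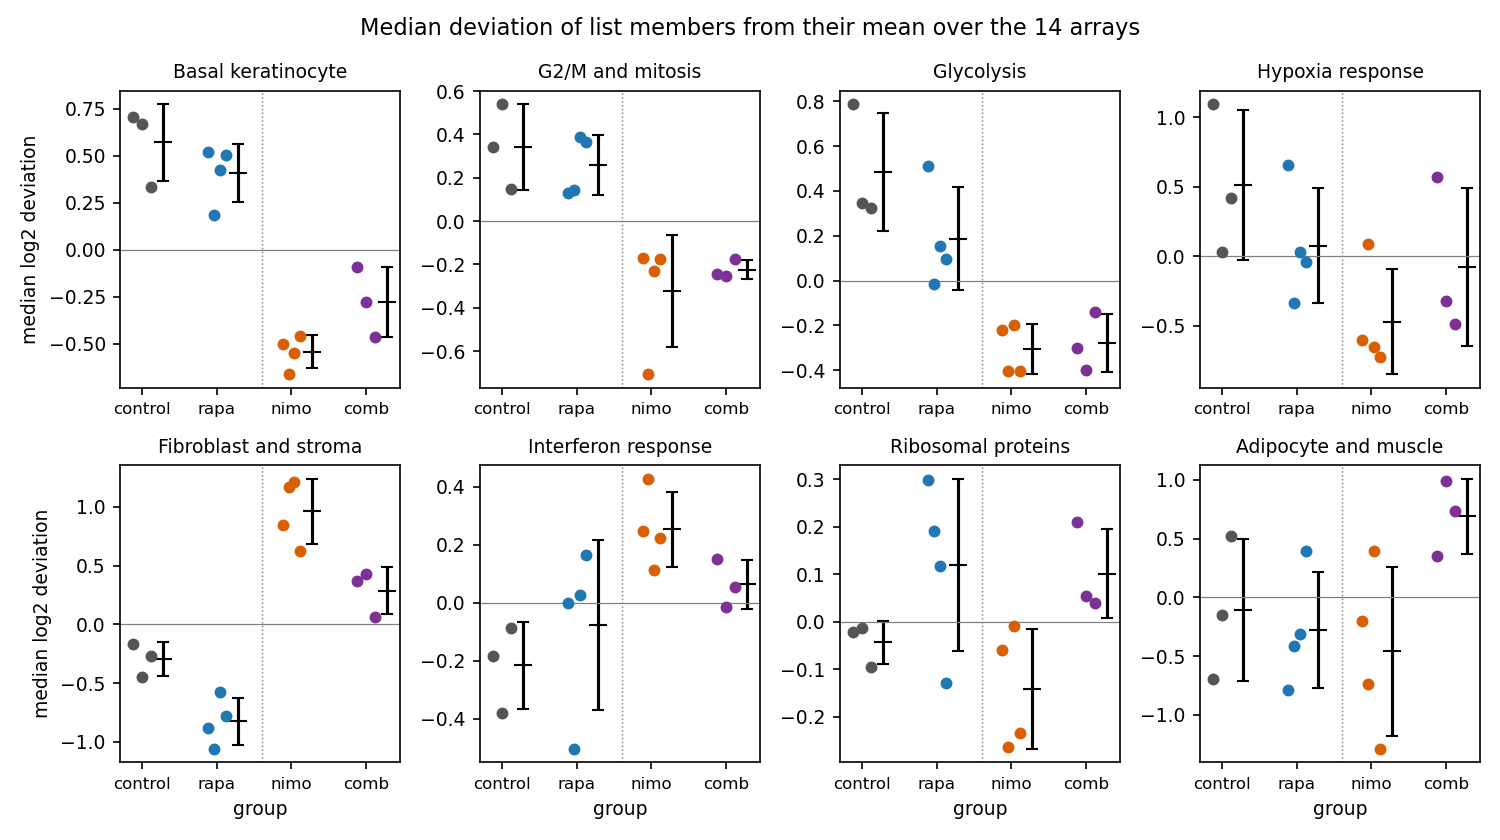
Median deviation of the members of 8 gene lists from their mean over the 14 arrays (log2, y axis), 1 point per array, by group. Fibroblast and stroma markers lie at −1.06 to −0.17 on the arrays of slide 1 and at 0.06 to 1.21 on those of slide 2, and slide and treatment cannot be told apart between these sets.

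The combination was compared with rapamycin, which addresses what nimotuzumab adds to rapamycin. Basal keratinocyte genes fell again (10 of 17 lower, median −0.75, adjusted p = 4.71e-10, and adjusted p = 0.147 with an estimated correlation). Genes of mitosis (5 of 31 lower, median −0.51, adjusted p = 1.29e-08), DNA replication (3 of 32, median −0.50, p = 1.85e-07) and glycolysis (3 of 19, median −0.46, p = 5.46e-06) fell, each with an adjusted p = 0.289 with an estimated correlation. Fibroblast and stroma markers rose (10 of 21 higher and 1 lower, median 1.06, adjusted p = 0.000508, and adjusted p = 0.289 with an estimated correlation). NF-kB and cytokine genes (6 of 25 higher, median 0.33, adjusted p = 0.0109) and endothelial markers (4 of 15 higher, median 0.36, p = 0.0187) rose, again with an adjusted p = 0.289 with an estimated correlation. For these, slide and treatment cannot be told apart.

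ITGA6 and CDH3 fell by 1.03 ± 0.16 (adjusted p = 0.00437) and 0.75 ± 0.13 (0.00804), and the nerve growth factor receptor NGFR by 1.87 ± 0.35 (0.00945). CDC20 fell by 1.41 ± 0.26 (adjusted p = 0.00972), BIRC5 by 0.90 ± 0.19 (0.0183), and FOXM1 by 0.84 ± 0.20 (0.0261). TK1 fell by 0.83 ± 0.19 (adjusted p = 0.0234), GINS2 by 0.88 ± 0.20 (0.0248) and MCM2 by 0.98 ± 0.27 (0.0492), and by 0.58 without combination 1. The glycolytic genes PKM, TPI1 and ENO1 fell by 0.75 ± 0.18 (adjusted p = 0.0258), 0.70 ± 0.17 (0.0267) and 1.06 ± 0.27 (0.0392). The receptor gene PDGFRA rose by 2.99 ± 0.38 (adjusted p = 0.00177), DCN by 2.26 ± 0.32 (0.00286) and COL5A2 by 1.63 ± 0.23 (0.00257). However, 0 of 2 other COL5A2 probes had the same sign and its call ended with the mean of all probes (0.24, adjusted p = 0.559). The cytokine LIF rose by 1.78 ± 0.28 (adjusted p = 0.00447), BIRC3 by 1.84 ± 0.36 (0.0125), and CXCL8, the interleukin 8 gene, was at least 3.40-fold higher (adjusted p = 0.00844). The vascular genes KDR (1.80 ± 0.35, adjusted p = 0.0114), PECAM1 (0.70 ± 0.14, 0.0152) and TIE1 (0.95 ± 0.21, 0.0209) rose. With normexp the calls ended for PECAM1 (0.18, adjusted p = 0.576), TIE1 (0.32, 0.303), CXCL8 (0.62, 0.057) and the endothelial list (adjusted p = 0.156). KDR (0.96), BIRC3 (0.89), NGFR (−0.82) and HLA-DMA (0.67) were smaller by over 1.5 times with normexp, and PDGFRA (1.56) with the mean of all probes, and were still called. In antigen presentation HLA-DMA rose (1.22 ± 0.24, adjusted p = 0.0135), but its other probe had the opposite sign and its call ended with the mean of both (0.49, 0.207), with PSMB8 at −0.62 ± 0.19 (0.0669). Slide and treatment cannot be told apart for these genes.

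Large increases in the combination against rapamycin were those of the matrix genes COMP (3.48 ± 0.83, adjusted p = 0.0285) and THBS4 (3.31 ± 0.74, 0.0219) and of ZIC1 (4.26 ± 1.07, 0.0348). ZIC1 was well above background on 1 of 4 rapamycin arrays, and differed by 2.64 with the others at the bound. Lower bounds were taken for FAM66E (at least 2.38-fold higher, adjusted p = 0.0189) and PODN (at least 3.77-fold, 0.00588). The FAM66E bound rested mostly on combination 2 (−1.09, against −5.00 to −4.43 on the others). With normexp the calls ended for ZIC1 (1.41, adjusted p = 0.126), FAM66E (0.68, 0.331) and PODN (0.74, 0.0936), while PHGR1 (−2.00) and IL7R (−1.12) were smaller by over 1.5 times and were still called. The largest declines without overlap of the groups were in PHGR1 (−3.13 ± 0.72, adjusted p = 0.0246), SFTPD (−3.08 ± 0.30, 0.000551), IL7R (−2.86 ± 0.31, 0.00081, with 1 of 3 combination arrays well above background), KANK4 (−2.50 ± 0.32, 0.00182) and MMP9 (−2.24 ± 0.62, 0.0492). EGFR (0.03 ± 0.23, adjusted p = 0.951), MTOR (−0.26 ± 0.20, 0.418) and FKBP1A (−0.65 ± 0.20, 0.0629) did not pass, and without combination 1 they lay at −0.32, −0.01 and −0.38. For these genes too, slide and treatment cannot be told apart.

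For the combination against rapamycin limma called 1593 features, 1150 higher and 443 lower (840 and 340 genes with a symbol), with 6501 at an unadjusted p under 0.05. The split was 834 higher and 870 lower with median scaling, 919 and 551 with quantile normalization and 490 and 300 with normexp. Antigen presentation (1 of 20 higher, median −0.27, adjusted p = 0.0142) and housekeeping genes (1 of 20 lower, −0.21, p = 0.0187) also fell as groups, each at an adjusted p = 0.289 with an estimated correlation. Mitochondrial respiration (2 of 25 lower, −0.07, adjusted p = 0.032) and the integrated stress response (3 of 31 lower, −0.21, p = 0.0325) fell, with an adjusted p = 0.549 and 0.382 with an estimated correlation. Without combination 1 these medians were −0.17 and −0.13, and that of mitochondrial respiration was −0.03 without combination 2 and −0.12 without rapamycin 1. Immediate early genes (3 of 21 higher and 1 lower, 0.53, adjusted p = 0.032) and EGFR ligands and receptors (2 of 13 higher, 0.49, p = 0.032) rose, with an adjusted p = 0.542 and 0.289 with an estimated correlation. Adjusted over the list alone, 12 basal keratinocyte, 16 mitosis, 16 G1/S, 5 glycolysis and 5 integrated stress response genes were lower and 13 fibroblast, 9 NF-kB, 6 endothelial and 9 immediate early genes were higher. In these counts slide and treatment cannot be told apart.

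The count of the combination against rapamycin was 731 without rapamycin 3, 859 without rapamycin 4 and 719 without combination 1. Without combination 1, calls ended for MCM2, ENO1, MMP9, PKM, TPI1, ZIC1, PHGR1, BIRC5, GINS2, FOXM1, COMP, THBS4 and HLA-DMA (adjusted p = 0.0516 to 0.136). Without rapamycin 3 they ended for the first 9 of these, TK1 and TIE1 (adjusted p = 0.0528 to 0.105). MCM2 lost its call on removal of any 1 of 11 arrays, MMP9 of 10, ENO1 of 9, ZIC1 of 5, PKM, TPI1 and PHGR1 of 4, FOXM1, GINS2 and COMP of 3, and BIRC5 and TIE1 of 2. MCM2, MMP9 and ENO1 also lost their calls with no filter (adjusted p = 0.0711, 0.0701 and 0.0575) or quantile normalization (0.0639, 0.0558 and 0.0507), MMP9 with the trend and robust options (0.06) or the series table (0.0507), and ZIC1 with no filter (0.0503). With only the arrays compared, calls ended for 20 genes, all called ones named in this comparison but CDC20, TK1, PDGFRA, DCN, COL5A2, LIF, CXCL8, PODN, SFTPD, IL7R, KANK4 and MMP9 (adjusted p = 0.0542 to 0.156). List calls ended for immediate early genes (without rapamycin 3, adjusted p = 0.0587, or combination 1, 0.0967), EGFR ligands (combination 1, 0.0995, or combination 3, 0.0575), and the integrated stress response (rapamycin 1, 0.0633, or combination 2, 0.0872). They ended too for mitochondrial respiration (rapamycin 2, adjusted p = 0.0929, or combination 2, 0.477), housekeeping genes (combination 2, 0.0693) and endothelial markers (combination 3, 0.0615). With normexp and with the filter on all 14 arrays, calls ended for mitochondrial respiration (adjusted p = 0.194 and 0.0879), the integrated stress response (0.16 and 0.0681), housekeeping genes (0.0696 and 0.0562) and endothelial markers (0.156 and 0.0605). With quantile normalization they ended for mitochondrial respiration (adjusted p = 0.251), the integrated stress response (0.158) and antigen presentation (0.0644), and with no filter for mitochondrial respiration (0.0739) and the integrated stress response (0.0887). With the mean of all probes they ended for EGFR ligands (adjusted p = 0.194), immediate early genes (0.104, and 0.0555 with only the arrays compared) and mitochondrial respiration (0.0618).

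The interaction asks whether the effect of rapamycin differed with and without nimotuzumab, and a constant difference between slides or rows cancels in it. It was positive for hypoxia genes (19 of 20 members above 0, median 1.02, adjusted p = 2.18e-06) and basal keratinocyte genes (14 of 17, median 0.49, adjusted p = 0.000281). It was negative for interferon-stimulated genes (29 of 36 below 0, median −0.32, adjusted p = 2.18e-06). With an estimated correlation the adjusted p = 0.552 for hypoxia genes and 0.532 for the other lists named here. The hypoxia median was 0.55 without combination 1 and 0.65 without control 1. The hypoxia genes P4HA2, BNIP3 and P4HA1 had interactions of 0.72 ± 0.26, 2.65 ± 0.99 and 1.27 ± 0.53. The interferon-stimulated genes IFIT3, OAS1 and IFI44L had −0.71 ± 0.21, −0.77 ± 0.27 and −0.92 ± 0.39, and CAV1, CDH3 and the basal transcription factor TP63 had 0.83 ± 0.27, 0.58 ± 0.19 and 0.59 ± 0.27. The glycolysis genes GPI, SLC16A3 and SLC2A1 had 0.80 ± 0.30, 0.93 ± 0.43 and 0.74 ± 0.35, and the stromal genes MMP2, DCN and THY1 −1.40 ± 0.57, −1.10 ± 0.45 and −0.57 ± 0.25. CD74, HLA-DMA and TAPBP of antigen presentation had −1.62 ± 0.56, −0.72 ± 0.35 and −0.39 ± 0.23. The lysosomal genes MCOLN1, GABARAPL1 and TPP1 had −1.07 ± 0.36, −0.52 ± 0.22 and −0.60 ± 0.33, and the cell cycle genes UHRF1 and RRM2 0.56 ± 0.20 and 0.49 ± 0.27. The cyclin gene CCNE2 and the receptor gene OR52H1 were positive but are given without a value, since CCNE2 was well above background on 0 of 4 rapamycin and 0 of 4 nimotuzumab arrays and OR52H1 on 0 of 4 nimotuzumab arrays. Other small p-values were those of the cytokine IL11 (1.41 ± 0.29), IGFBP2 (1.75 ± 0.37), and on the negative side of CTPS2 (−1.20 ± 0.23) and SLC11A1 (−1.17 ± 0.26). EGFR had 0.57 ± 0.33, MTOR −0.51 ± 0.28 and FKBP1A −0.22 ± 0.28. Without combination 1 the values were 1.74 for BNIP3, 0.34 for TP63, 0.52 for GPI, 0.61 for SLC16A3, 0.42 for SLC2A1, −0.81 for MMP2, −0.23 for TAPBP, −0.22 for TPP1, 0.28 for RRM2, 0.22 for EGFR, −0.26 for MTOR and 0.06 for FKBP1A.

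No feature passed for the interaction by limma (0 called, smallest adjusted p = 0.869, 1041 at an unadjusted p under 0.05, and 0 with the trend and robust options). The adjusted p was 0.017 for antigen presentation (median −0.12) and for lysosome and autophagy (−0.13), 0.0233 for fibroblast markers (−0.24), 0.0312 for glycolysis (0.35), and 0.0468 for G1/S (0.19) and for adipocyte and muscle markers (1.06). With an estimated correlation these gave, in the same order, an adjusted p = 0.532, 0.225, 0.552, 0.744, 0.935 and 0.532. Adjusted over the list alone, 1 G1/S gene passed. The median of antigen presentation was −0.25 to −0.08 without control 2, control 3, rapamycin 2, nimotuzumab 2 or combination 3, and of lysosome −0.25 without control 2 and −0.22 without rapamycin 3. Glycolysis lay at 0.22 without nimotuzumab 2 and 0.21 without combination 3, and fibroblast markers at −0.39 without combination 2. G1/S lay at 0.07, 0.29 and 0.06 without control 2, control 3 and nimotuzumab 2, and adipocyte markers at 1.61, 1.81 and 2.10 without control 1, rapamycin 4 and nimotuzumab 3. The calls of hypoxia, the interferon response and basal keratinocyte genes held without each array in turn. The calls ended for antigen presentation (without rapamycin 1, adjusted p = 0.0638), lysosome (without combination 2, 0.0749) and fibroblast markers (without control 2, rapamycin 3 or combination 3, up to 0.216). They also ended for glycolysis (6 arrays, up to an adjusted p = 0.365 without combination 3), G1/S (5 arrays, up to 0.782 without nimotuzumab 2) and adipocyte markers (9 arrays, up to 0.354 without combination 3). With no filter the calls ended for adipocyte markers (adjusted p = 0.412), fibroblast markers (0.1), lysosome (0.138) and antigen presentation (0.0769), and with normexp for lysosome (0.443) and antigen presentation (0.274). With the filter on all 14 arrays they ended for adipocyte markers (adjusted p = 0.161), G1/S (0.0811) and antigen presentation (0.0623), with the mean of all probes for adipocyte markers (0.0573) and G1/S (0.063), and with median scaling for G1/S (0.0912).

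Across genes, which are not independent replicates, the rapamycin effect without nimotuzumab correlated with that on top of nimotuzumab at r = 0.263 (Spearman's rho = 0.257), with 59.2% of the features moving the same way. With normexp these were r = 0.221, rho = 0.0948 and 51.4%, near an even split. Groups simulated without any change gave 0.00056. These 2 comparisons shared no array, but both set row 2 against row 1 of a slide, so a row effect alone would also give a positive r. The nimotuzumab effects with and without rapamycin correlated at r = 0.685, with 767 features called higher in both (75.6 expected by chance) and 271 lower in both (21.2 expected), and slide and treatment cannot be told apart in either. Against the shared control, rapamycin and nimotuzumab correlated at r = 0.336 (simulated 0.573, covariance 0.0643 against 0.062), and rapamycin and the combination at r = 0.475 (simulated 0.536, covariance 0.101 against 0.062). Nimotuzumab and the combination correlated at r = 0.764 (simulated 0.536, covariance 0.304 against 0.062). The last pair shared 1007 features called higher and 546 lower (113.2 and 48.8 expected without a shared control). Both set slide 2 against slide 1, so slide and treatment cannot be told apart in these values. With the control arrays divided between the comparisons, added after the results were seen, r was 0.0027 to 0.184, 0.0817 to 0.348 and 0.530 to 0.647 for these 3 pairs against control.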

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

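The tests of a mouse RNA share and of the spike-ins in this part were written after the results they measure had been seen. Single genes and lists stand here because 1 array lay far from the other 3 of its group (a gap to the nearest array, as a share of the group's range, over Dixon's critical value, tested for 138 genes and 4 array measures), or because the interaction of a gene list passed. The splits had been planned, and the slide difference, combination 1 and the ribosomal shift were chosen after the results had been seen.

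Of 284 tests for an outlying array, 9 passed that limit, and chance alone passes about 1 in 20 of such tests. Nimotuzumab 2 had 5 of the 9: CLIC5 (gap 0.924, −3.85 against −7.62 to −7.33 on the other arrays, which are surrogate values, as only 1 of 4 was well above background), GABARAPL1 (0.887, 1.33 against 0.98 to 1.02), CHAF1A (0.852, 0.33 against 0.66 to 0.71), QPRT (0.842, −2.22 against −1.53 to −1.40) and MCM2 (0.830, 2.36 against 2.79 to 2.88). Rapamycin 1 had MCM6 (0.887, 2.12 against 2.44 to 2.48) and PFKP (0.839, 4.99 against 4.40 to 4.50). Rapamycin 4 had STAT2 (0.870, −2.74 against −3.18 to −3.12) and rapamycin 2 had ISG15 (0.833, 5.63 against 6.23 to 6.35).

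The rapamycin effect differed with and without nimotuzumab, by the camera test of the interaction, for 9 lists. The adjusted p was 2.18e-06 for the hypoxia response (median 1.02) and the interferon response (−0.32), 0.000281 for basal keratinocyte genes (0.49), 0.0170 for lysosome and autophagy (−0.13) and antigen presentation (−0.12), 0.0233 for fibroblast and stroma markers (−0.24), 0.0312 for glycolysis (0.35), and 0.0468 for G1/S and DNA replication (0.19) and for adipocyte and skeletal muscle markers (1.06). None of the 9 passed with an estimated correlation, where the adjusted p ranged from 0.225 to 0.935.

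The arrays of slide 2 differed from those of slide 1 in 2800 features for nimotuzumab against control. Probe GC content is argued against as the whole cause here. With each array's GC trend removed, 3035 features were called, 2559 of them among the first 2800. GC stays open for the combination, whose difference had an r with GC of −0.301 against nimotuzumab and −0.145 against control (−0.281 for the interaction). With the trend removed, 5 features were called against nimotuzumab, and 1488 of 3492 against control were higher. Slide and treatment cannot be told apart, because 0 groups had arrays on both slides. A larger share of mouse RNA may also have contributed and cannot be told apart from treatment. Of 5 other host lists, 0 had an upper quartile below the fibroblast lower quartile (0.19). This test cannot decide it, as equal rises of host lists were assumed. Medians were 1.09 for fibroblast, 0.49 for endothelial, 0.27 for adipocyte and muscle, 0.25 for erythroid, 0.16 for lymphoid and 0.04 for macrophage markers. A biological effect of nimotuzumab stays open as well, as a hypothesis.

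Combination 1 stood apart from the other arrays, with deviations of SD 0.564 against 0.279 to 0.429. Probe GC content is argued against as the whole cause, since the SD was 0.522 after its trend was removed, against at most 0.420 on the others. The median scaled log2 signal of its spike-ins was 1.17 against 3.63 to 5.57 on the other 13 arrays, so another amount of spike-in or of labelled RNA on that array is a candidate explanation. No biological explanation was tested, and a difference of that tumour stays open.

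The upward shift of ribosomal protein genes in rapamycin against control was small, with a median of 0.16. The brightness of the probes is argued against, since the median lay at percentile 100 of 10000 lists matched on signal (−0.03 to 0.04). The dim array rapamycin 1 is argued against as the sole source, since without it 67 of 76 members stayed above 0 (median 0.10, camera adjusted p = 0.000103). Correlation between the genes stays open (adjusted p = 0.58 with an estimated correlation), as do the overall signal of each array, since rapamycin 4, the brightest of its group, lay at −0.13 and the controls at −0.10 to −0.01, the slide row, which cannot be told apart from treatment, and a response to rapamycin, as a hypothesis.

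Splits of the arrays were compared with the real groups for each count of called features. Only 1 of 35 splits, the real one, gave as many for nimotuzumab against control (2800, the highest other 197) and for the combination against rapamycin (1593, the highest other 71). That is the smallest share 35 splits allow, unadjusted over comparisons, and slide and treatment cannot be told apart in both. For the combination against control, the 10 splits are too few for a share under 0.05 (1 of 10 gave as many, 2743, the highest other 1). Where 0 features were called, every split gave at least as many by construction. The splits decide nothing for rapamycin against control (the highest other 1), the combination against nimotuzumab (the highest other 4) or the interaction (100 drawn, the highest other 21).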

How the results depend on the processing

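All alternatives here had been planned. The well above background call limits what dim genes can show, so the differences of genes near background depend on the surrogate values.

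Rapamycin against control called 1 feature with quantile normalization, median scaling, the filter on all 14 arrays, or the trend and robust options, 3 with slide as a block, and 0 to 1 without single arrays. The combination against nimotuzumab called 6 with normexp, 3 with the filter on all 14 arrays, 9 with the trend and robust options, 1 with only the arrays compared, 3 with slide as a block, and 0 to 8 without single arrays. The combination against control called 363 with only the arrays compared, 1506 at a fold of at least 2, and 661 to 3074 without single arrays. Nimotuzumab against control called 3616 with only the arrays compared, 1420 at that fold, and 1208 to 3922 without single arrays. The combination against rapamycin called 790 with normexp, 363 with only the arrays compared, 945 at that fold, and 719 to 1786 without single arrays. The interaction called 0 without single arrays. The fold adds a second limit to the same calls and a fit of 6 or 7 arrays has fewer degrees of freedom; the cause of the other changes was not tested.

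Of the 69 list calls, 1 passed with an estimated correlation and 38 lists passed with fry, 33 of them from the 69, against 61 to 74 without single arrays. With normexp, r was 0.470 for rapamycin and nimotuzumab, 0.569 for rapamycin and the combination, and 0.635 for nimotuzumab with and without rapamycin. Without single arrays r was 0.187 to 0.343 for rapamycin with and without nimotuzumab, 0.272 to 0.451 and 0.399 to 0.571 for rapamycin with nimotuzumab and with the combination, 0.698 to 0.795 for nimotuzumab with the combination, and 0.612 to 0.712 for nimotuzumab with and without rapamycin.

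The replicate numbers did not pair the arrays, since the r of 19 same-number pairs was −0.214 to 0.239, with 6 over 0.1, and 5 of the 14 arrays correlated best with their own number. With the replicate number as a block the counts were 0, 2315 and 2039 against control for rapamycin, nimotuzumab and the combination, 0 for the combination against nimotuzumab, 697 against rapamycin and 0 for the interaction. Of 108 calls of named genes, 45 ended with only the arrays compared, 21 with the replicate block, 10 with normexp, 8 with no filter, 6 with quantile normalization, 6 with the mean of probes, 2 with the trend and robust options, 1 with the series table and 0 with median scaling. The filter on all 14 arrays ended 0 of 85. Of the 69 list calls, 13 ended with the filter on all 14 arrays, 13 with the mean of probes, 9 with quantile normalization, 7 each with normexp, no filter or the replicate block, 3 with median scaling, 1 with the series table and 0 with the trend and robust options. Of the values of the 108 calls, 35 were smaller by over 1.5 times with normexp and 6 with the mean of probes. No value turned its direction as a call.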

Other observations

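Several gene groups that did not pass in nimotuzumab against control held genes that were called in it, where slide and treatment cannot be told apart. The genes in this paragraph and the next were chosen after their values were seen. Macrophage and myeloid markers did not pass as a list (4 of 20 higher and 1 lower, median 0.04, mean 0.43, adjusted p = 0.14). LYZ, the lysozyme gene, rose by 2.87 ± 0.31 (adjusted p = 0.000212) and C1QB, a complement gene, by 2.26 ± 0.26 (adjusted p = 0.000267), while the integrin gene ITGAX fell by 1.1 ± 0.32 (adjusted p = 0.0426). Antigen presentation genes did not pass (2 of 20 higher, median −0.20, mean 0.08, adjusted p = 0.462), though the class II genes CD74 (2.85 ± 0.40, adjusted p = 0.000847) and HLA-DMA (1.95 ± 0.24, adjusted p = 0.000449) rose. Keratinocyte differentiation did not pass (7 of 37 lower, median 0.05, mean −0.25, adjusted p = 0.285), but the wound keratins KRT6A (−1.09 ± 0.24, adjusted p = 0.0124) and KRT16 (−1.52 ± 0.38, adjusted p = 0.0212) fell. Among epithelial-mesenchymal transition genes (4 of 19 higher and 3 lower, median −0.33, adjusted p = 0.285), the transcription factor genes TWIST1 (2.40 ± 0.27, adjusted p = 0.000282) and ZEB2 (2.52 ± 0.34, adjusted p = 0.00077) rose and TGFBI fell (−2.00 ± 0.22, adjusted p = 0.000212).

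Genes of FOXO and insulin feedback just missed the limit (5 of 20 higher and 1 lower, median 0.25, adjusted p = 0.053), with KLF9 2.66 ± 0.27 higher (adjusted p = 0.00016). The desaturase genes FADS1 (−1.02 ± 0.19, adjusted p = 0.00434) and FADS2 (−1.09 ± 0.24, adjusted p = 0.012) fell within the list of fatty acid synthesis, which did not pass (3 of 14 lower, median −0.15, adjusted p = 0.183). Components of mTOR did not pass either (1 of 25 higher and 1 lower, median −0.15, adjusted p = 0.401). For these, slide and treatment cannot be told apart.

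The closest arrays, rapamycin 3 and rapamycin 4, had r = 0.990 and a median absolute difference of 0.185, and 0 pairs of arrays were identical.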
